A study of Homo sapiens with 12 samples.

How the data were processed

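Total RNA of 4 untreated cell lines was labelled with biotin and measured on 12 arrays, 3 per line, with the array type named as Human Gene 1.0 ST in the deposited RNA quality sheets. Groups were taken from the cell line, tissue and phenotype fields of the labels. The deposited values are log2 expression values per probe set, made by the authors with RMA and Partek per the submitters' processing notes, and the versions are not given in the sources used here. As usually run, RMA corrects background, normalizes arrays to a common distribution and summarises probes on a log2 scale, which limits differences between arrays and compresses those of dim probe sets. The deposited workbook also holds p-values and step-up adjusted p-values from a model with tissue, sensitivity and their interaction, and log2 ratios of group means, per the file headers. The sheet of genes decreased in sensitive lines has a header that names log2 ratios, but its values equal signed linear folds of the same probe sets within 0.0001, so its own values were not used and the log2 ratios of the full results sheet took their place.

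Every value of the results sheet matched the value table within a tolerance of 0.0001, with 0 probe sets differing. In a secondary sheet of 225 selected genes, 152 hold the same value, 6.68914, in replicate 3 of HCT15, and in the sheet behind the all-gene heat map 4 of 26890 lines match no probe set of the results sheet. These sheets were used for checks alone. Of the 26890 probe sets, 19305 carry 1 gene symbol, 1750 several and 5835 none in the platform annotation, which can be old. Symbols were looked up in the RefSeq gene table by gene ID, which updated 0 symbols, and 18343 of the 18374 genes were found there. Probe sets with several symbols or none were tested but not named. Each of the 684 genes with more than 1 probe set was represented by the one with the highest mean over all arrays. Per-sample columns left without a sample numbered 0.

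Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with a mean per cell line, lmFit and eBayes on the log2 values and Benjamini-Hochberg adjustment over all 26890 probe sets, all p-values being two-sided. A gene was called at an adjusted p under 0.05 and at least a 2-fold difference. The contrasts were HT29 minus HCT15, PC9 minus HCC827, their average, their difference (the interaction), and the mean of the colon lines minus that of the lung lines. All 12 arrays entered 1 model so that the lines shared 1 estimate of the spread. The arrays' spread is the only error in these p-values, and the average over tissues and the comparison of colon with lung lines were therefore also fitted on 4 line means and with cell line as a random block. The random block shares 1 correlation among all genes and still counts arrays as samples, so it is not a test with the line as the unit. Recomputing the authors' model without moderation gave log10 p-values within 0.0054 of those in the authors' deposited table. At an adjusted p under 0.05 and a 2-fold difference the authors' deposited table holds 1676 probe sets in colon and 1821 in lung.

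The design, the 31 gene lists, the alternatives and the rule for named genes were fixed before the data were examined, apart from the cell-line fits of colon against lung lines, which were added after. The rule took the 12 highest and 12 lowest called genes of each tissue whose arrays did not overlap between lines, which chance gives for 10% of genes with 3 against 3. It took 12 of each sign shared by both tissues, 6 of each opposite orientation, 8 of each sign between tissues, up to 4 called members of each list, 12 genes given whatever their values, and members of the study's autophagy sheet and short table of genes higher in sensitive lines that were called in both tissues. Symbols of pseudogenes, antisense, small RNA and olfactory receptor genes were not eligible, and genes of the sex chromosomes that report sex were counted but not named. The lists hold 753 different genes, of which 679 were analysed and 74 not analysed here. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 31 lists of a comparison. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. The median, mean and camera direction of a list differed in sign in 25 of 155 pairs of list and comparison, of which 0 passed the threshold.

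The steps were tested on simulated data with 200 of 26890 probe sets changed between HT29 and HCT15. Of 50 changed by 2.5-fold, 50 were called, as were 50 of 50 at 4-fold and 50 of 50 at 8-fold. Of 50 changed by 1.5-fold, 0 were called under the 2-fold minimum and 41 passed the adjusted p. Unchanged probe sets called numbered 0, and 0 of 31 lists passed. Probe sets were simulated independently of each other, so the list result does not cover lists whose genes vary together. Alternatives were quantile normalization, median centring, leaving out dim probe sets, eBayes with trend and robust settings, the unmoderated model, the arrays of 1 tissue alone, a replicate term, other thresholds including limma treat, averaged probe sets, the workbook's values and leaving out each array. Splits of the arrays numbered 10 within a tissue and 100 in the comparisons over all arrays. Gene order along chromosomes came from the start positions in the RefSeq gene table, and distances between genes were not used. Figures and order-based tests used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.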

Results

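Gene expression was measured on arrays in 4 established human cancer cell lines that received no drug, with 3 arrays per line. HT29 and HCT15 are colon carcinoma lines, and PC9 and HCC827 are lung adenocarcinoma lines. The labels class HT29 and PC9 as HCQ-S and HCT15 and HCC827 as HCQ-R, read here as sensitive and resistant to hydroxychloroquine, a drug that gathers in lysosomes and blocks autophagy. The titles of the HCT15 arrays spell the line HCT115, and the cell line field was followed. Values were log2 intensities of 26890 probe sets and ran from 2.85 to 14.07, with array medians between 7.301 and 7.421. Across probe sets, arrays of a line correlated at 0.9967 to 0.9985, arrays of the other line of the same tissue at 0.9585 to 0.965, and arrays of the other tissue at 0.9462 to 0.9513. Of all pairs of arrays, 0 held identical values. The labels do not say whether the 3 arrays of a line came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Each phenotype was represented by 1 line per tissue, and the number of arrays limits the precision. Counts refer to 18374 genes with a single symbol. A gene was called at a limma adjusted p under 0.05 with at least a 2-fold difference, and counts of list members as higher or lower are of called members. Signal near background compresses differences, so a difference from a dim level is a lower limit of its size.

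The first comparison asked which genes differed between the sensitive and the resistant colon line. LYZ, which encodes the antibacterial enzyme lysozyme, was higher in HT29 than in HCT15 by 8.46 ± 0.06 on the log2 scale (SE, n = 3 and 3). ALDH1A1, a retinaldehyde dehydrogenase, was higher by 7.29 ± 0.06 and stood at 12.01 ± 0.03 in HT29 against 4.72 ± 0.07 in HCT15 (mean ± SD). TM4SF4 (6.75), the glutathione peroxidase gene GPX2 (6.61), the aldo-keto reductase gene AKR1B10 (6.38), the scramblase gene ANO6 (6.32) and the matrix metalloprotease gene MMP7 (6.24) were also higher in HT29, as were POF1B (6.04), MSN (5.89), ANXA10 (5.89), AGR2 (5.87) and the fatty acid receptor gene FFAR4 (5.77). The oxidized lipoprotein receptor gene OLR1 was lower in HT29 by −7.24 ± 0.07. LEF1, a transcription factor of Wnt signalling, was lower by −5.89, and HLTF, a helicase-like DNA translocase of DNA damage tolerance, by −5.55 ± 0.09, at 4.60 ± 0.22 in HT29 against 10.15 ± 0.01 in HCT15. TMEM52B (−5.79), FAM171B (−5.17), the glucose transporter gene SLC2A3 (−5.16), the drug efflux pump gene ABCB1 (−4.88), HDGFL3 (−4.49), the lysosomal galactosylceramidase gene GALC (−4.41), CHN1 (−4.38), GSTM3 (−4.21) and OXCT1 (−4.20) completed the 12 lowest. In total 1449 genes were called, 784 higher and 665 lower in HT29, or 7.9% of genes, and the largest adjusted p among them was 0.000898.

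Genes of the intestinal epithelium were higher in HT29. Of 28 measured members, 12 were called higher and 3 lower, with AGR2 at 5.87, the tetraspanin gene TSPAN8 at 5.69, the galectin gene LGALS4 at 5.55 and REG4 at 5.38 (camera adjusted p = 3.35e-05). Stem-cell markers were higher in 6 and lower in 2 of 19 members, led by CD24 (5.62), PROM1 (5.59), the R-spondin receptor gene LGR5 (4.46) and the chemokine receptor gene CXCR4 (3.78), with an adjusted p of 0.000528. Retinoid metabolism and signalling had 4 of 20 members higher and 0 lower, among them the retinol-binding protein gene RBP4 (2.63) and the retinol dehydrogenase gene DHRS9 (2.34), with an adjusted p of 0.000774. These 3 lists also passed with an estimated correlation, each with an adjusted p of 0.0316.

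The list of NRF2 targets and glutathione enzymes, which detoxify electrophiles and peroxides, had 7 of 25 members higher and 1 lower (adjusted p = 6.05e-05; adjusted p = 0.0552 with an estimated correlation). GPX2, AKR1B10 and AKR1C2 (4.13) were higher, and GSTM3 was the lower member. Cholesterol synthesis had 2 of 18 members higher, SQLE (1.76) and HMGCS1 (1.67), both enzymes of the pathway, with an adjusted p of 2.04e-05 (adjusted p = 0.166 with an estimated correlation). The ERBB list had 6 of 25 members higher, including the receptor gene MET (1.502), the ligand gene TGFA (1.30), and DUSP4 (1.58) and SPRY4 (1.51), which are known to restrain ERK signalling (adjusted p = 0.000847; adjusted p = 0.275 with an estimated correlation). Epithelial junction and keratin genes had 4 of 28 members higher, led by KRT20 (5.73) and CLDN1 (2.32), with an adjusted p of 0.0252 (adjusted p = 0.166 with an estimated correlation). Of 40 cell cycle genes 0 were called, and their median was −0.23 (adjusted p = 0.000847; adjusted p = 0.508 with an estimated correlation). Among the 155 pairs of list and comparison, the count of called members was the same in all but 0 when adjusted over the list alone.

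The lung comparison asked the same of PC9 and HCC827. CASP14, a caspase of keratinizing cells, was higher in PC9 than in HCC827 by 6.96 ± 0.09 (SE, n = 3 and 3), and the aldo-keto reductase gene AKR1C2 was higher by 6.25 ± 0.07. VGLL1 (6.10), the heparan sulfatase gene SULF2 (6.08), the metalloprotease inhibitor gene TIMP3 (6.04), MAL (5.99), the sialic acid synthesis gene GNE (5.59), the calcium-activated chloride channel gene ANO1 (5.40), EPHX3 (5.38), CST1 (5.22), the squamous keratin gene KRT13 (5.10) and CMBL (5.10) followed. TM4SF18 was lower in PC9 by −7.17 ± 0.05, and DPP4, a surface dipeptidyl peptidase, by −6.74 ± 0.08. HPGD, which degrades prostaglandins (−5.99), the nucleic acid sensor gene IFI16 (−5.92), the TLR4 coreceptor gene LY96 (−5.92), HAVCR1 (−5.82), the proteoglycan gene VCAN (−5.76), BICC1 (−5.65), the transcriptional repressor gene ID2 (−5.54), HHLA2 (−5.44), NRK (−5.32) and GALNT5 (−5.19) were lower as well. In total 1504 genes were called, 694 higher and 810 lower in PC9, or 8.2% of genes, and the largest adjusted p among them was 0.00196.

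The type I interferon response differed more than any other list in lung by median: 26 of its 36 measured members were called lower in PC9 and 0 higher, and the median was −1.91. IFI44L (−5.11), SAMD9L (−4.39), IFI44 (−4.03) and IFI6 (−3.99), all known to be induced by interferon, led the list (camera adjusted p = 4.46e-18; adjusted p = 0.062 with an estimated correlation). Antigen presentation had 6 of 18 members lower and 0 higher, among them the cathepsin gene CTSS (−2.86), the immunoproteasome gene PSMB9 (−2.07) and the class I light chain gene B2M (−1.11), with an adjusted p of 9.4e-06 (adjusted p = 0.0222 with an estimated correlation). The NRF2 and glutathione list had 8 of 25 members higher and 0 lower, with AKR1C2 at 6.25, AKR1B10 at 4.48, AKR1C3 at 3.90 and GPX2 at 3.58 (adjusted p = 5.2e-08; adjusted p = 0.0245 with an estimated correlation).

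Cholesterol synthesis had SQLE (1.30) and HMGCS1 (1.25) higher in PC9 and the sterol carrier gene STARD4 lower at −3.75, of 18 members (adjusted p = 0.0116; adjusted p = 0.745 with an estimated correlation). In the cell cycle list the cyclin gene CCNE1 was higher (1.33), and the mitotic kinase gene AURKB (−1.36) and the phosphatase gene CDC25C (−1.12) were lower, of 40 members with a median of −0.25 (adjusted p = 0.00389; adjusted p = 0.763 with an estimated correlation). Markers of lung epithelium were lower in 6 of 23 members and higher in 0, including the alveolar aspartic protease gene NAPSA (−4.35), the lung lineage factor gene NKX2-1 (−2.60) and the surfactant lipid transporter gene ABCA3 (−1.51), and the list missed the threshold with an adjusted p of 0.0619. Of 28 mesenchymal markers 8 were lower and 2 higher, with an adjusted p of 0.288. VIM, the mesenchymal intermediate filament gene, was lower by −2.95 and the receptor kinase gene AXL was higher by 2.83.

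The sensitive lines were then compared with the resistant lines across both tissues. AKR1C2 (4.13 in colon, 6.25 in lung), AKR1B10 (6.38 and 4.48) and AKR1C3 (3.83 and 3.90), aldo-keto reductases that reduce carbonyls and steroids, were higher in both sensitive lines, as were the calcium-binding protein gene CALB2 (5.05 and 5.02), GPX2 (6.61 and 3.58), SULF2 (3.91 and 6.08) and ANO1 (3.86 and 5.40). GALNT14 (3.66 and 3.71), the neurotensin receptor gene NTSR1 (5.10 and 3.59), the chromatin organizer gene SATB1 (3.24 and 3.72), the hyaluronan-degrading CEMIP (3.18 and 3.24) and the lipopolysaccharide receptor gene TLR4 (2.98 and 4.30) shared this direction. GALC was lower in both by −4.41 and −4.48, VPS35L, a subunit of an endosomal recycling complex, by −3.87 and −3.73, and MPP1 by −3.76 and −3.40. RRAGD, a lysosomal GTPase that signals to mTORC1, was lower by −3.90 and −2.69. SRPX (−3.05 and −2.55), MYBL1 (−2.62 and −2.76), ZNF462 (−2.66 and −2.89), GSPT2 (−2.90 and −2.41), the growth factor gene FGF2 (−3.21 and −2.33), RAB3B (−2.31 and −2.84), KHDRBS3 (−2.29 and −2.79) and INTS6L (−2.29 and −3.06) were also lower in both.

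In these comparisons 144 genes were called higher in both sensitive lines and 106 lower in both, 250 in the same direction, against 58.9 for independent lists of these sizes. Another 192 genes were called in opposite directions, against 59.7 for independent lists. Both counts exceeded that baseline, which takes every gene as equally likely to be called, so the excess alone does not show a shared direction. The colon and lung comparisons share no array. Across the 18374 genes, which are not independent replicates, the colon and lung differences correlated at a Pearson r of 0.041 and a Spearman rho of 0.081. Of the genes called in 1 tissue alone, 782 of 1007 in colon and 857 of 1062 in lung also had a called difference between the tissues.

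**Figure D1:**
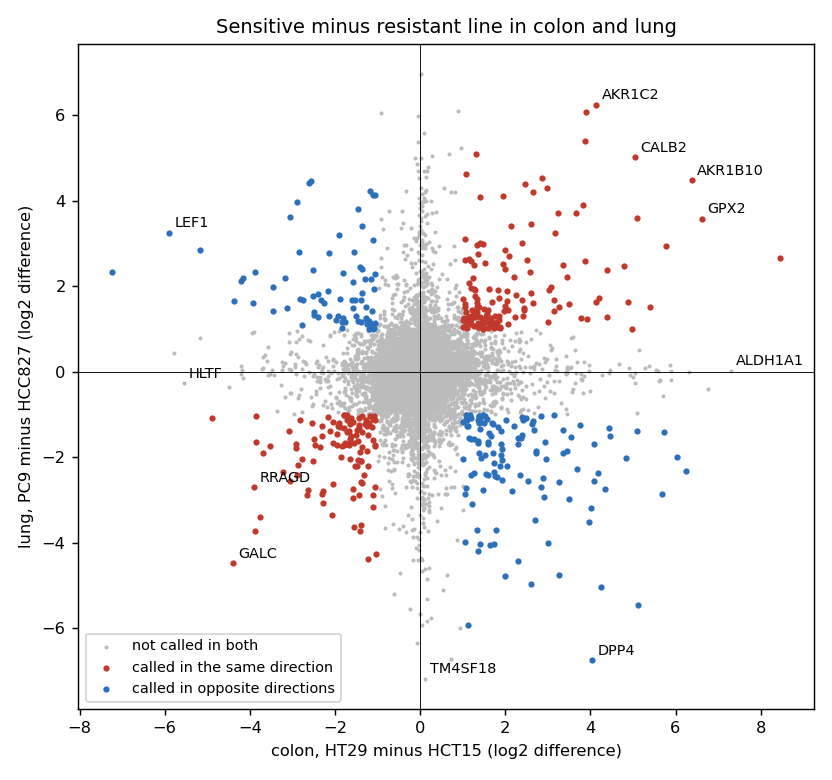
Log2 difference of genes between the sensitive and the resistant line in colon (x axis) and lung (y axis), where each point is 1 gene. Genes of the sex chromosomes that report sex are among the 18374 genes counted but are not drawn. Red marks genes called in the same direction, with AKR1C2 at 4.13 and 6.25, and blue those called in opposite directions, with DPP4 at 4.05 and −6.74. The full counts, 250 and 192, include any such genes that are not drawn.

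In the average over both tissues 989 genes were called, 510 higher and 479 lower in the sensitive lines. AKR1B10 averaged 5.43, AKR1C2 5.19 and GPX2 5.10, and GALC averaged −4.44. The NRF2 and glutathione list was higher, with 7 of 25 members higher and 1 lower (adjusted p = 1.4e-07; adjusted p = 0.0251 with an estimated correlation). Intestinal epithelium (10 of 28 higher, 1 lower, adjusted p = 4.34e-05), stem-cell markers (6 of 19 higher, 2 lower, adjusted p = 0.000609) and antigen presentation (5 of 18 lower, 0 higher, adjusted p = 0.000327) also held with an estimated correlation, each with an adjusted p of 0.0251. In lung alone intestinal epithelium had 4 members higher and 3 lower (adjusted p = 0.568) and stem-cell markers 1 and 1 (adjusted p = 0.617), and in colon alone antigen presentation had 2 higher and 4 lower (adjusted p = 0.163). PSMB9 (−1.53), TAP1 (−1.60) and HLA-DPA1 (−1.44), genes of peptide processing and display, were among the lower members of the last list. Type I interferon response had 15 of 36 members lower, with IFITM3 at −2.30 and HERC5 at −2.30 (adjusted p = 1.14e-09; adjusted p = 0.138 with an estimated correlation), but in colon alone 8 were higher and 5 lower (median 0.24). Cholesterol synthesis was higher at an adjusted p of 9.47e-05 (adjusted p = 0.232 with an estimated correlation), with 2 of 18 members higher, SQLE at 1.53 and HMGCS1 at 1.46, and 1 lower, STARD4 at −1.88. Retinoid metabolism was higher at 0.0229 (adjusted p = 0.112 with an estimated correlation), with 6 of 20 members higher, among them RARRES1 at 2.06, and 1 lower. Cell cycle genes were lower at an adjusted p of 0.000251 (adjusted p = 0.435 with an estimated correlation), with 1 of 40 called, AURKB at −1.07. With the 4 line means as the unit limma called 0 genes in this average, with a smallest adjusted p of 0.824 and 1319 genes at an unadjusted p under 0.05. That fit sets 3 coefficients on 4 values and has little power, so its 0 does not decide whether genes differ across lines. With cell line as a random block, where arrays still count as samples, limma called 758.

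**Figure D2:**
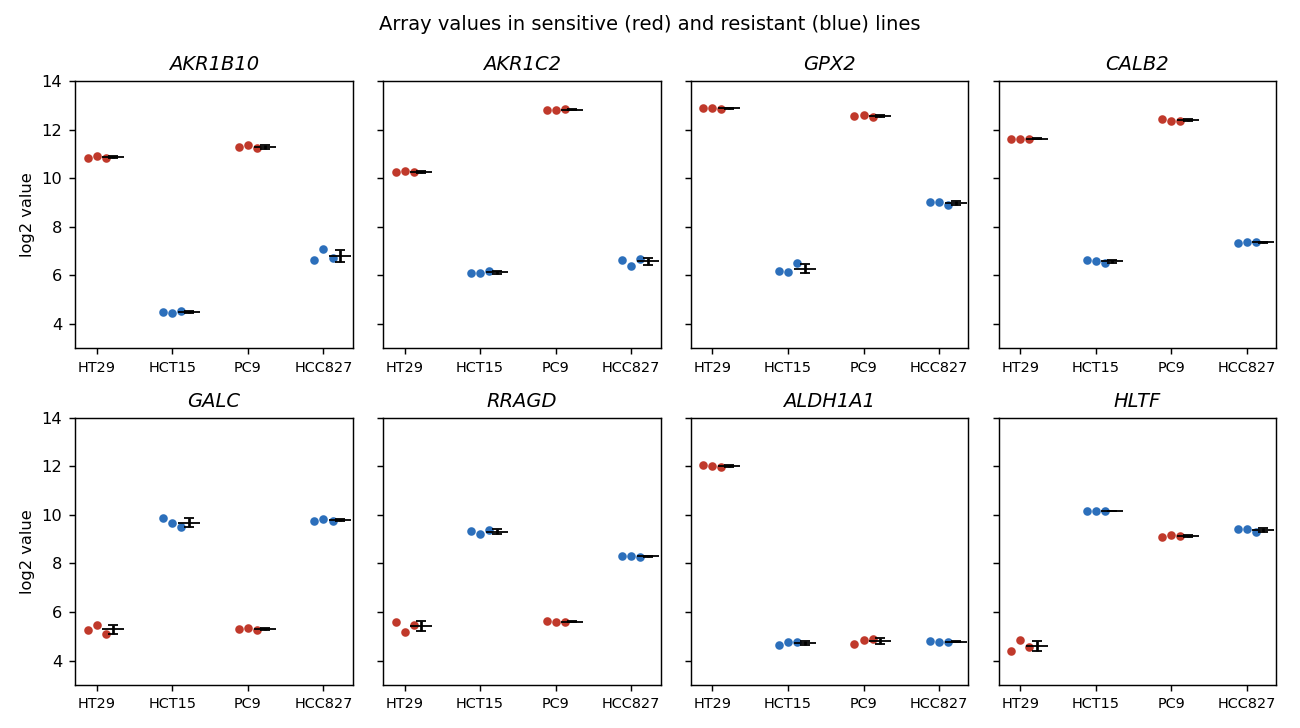
Log2 values of 8 genes on the 3 arrays of each line, with red points for the sensitive lines and blue for the resistant lines, and black marks for the mean and SD. GALC stood at 5.28 in HT29 and 5.30 in PC9 against 9.68 in HCT15 and 9.78 in HCC827, while ALDH1A1 stood at 12.01 in HT29 and at 4.81 in PC9.

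The 3 autophagy lists did not pass camera's test against other genes in colon or lung, while single members were called. Of 23 genes of autophagy initiation and nucleation, 3 were lower in HT29, ULK2 (−2.12), ATG2B (−1.37) and ATG14 (−1.15), and 1 was higher in PC9, WIPI1 (1.43), with adjusted p-values of 0.767 in colon and 0.949 in lung. Fry, which asks whether a list moved in 1 direction without setting it against other genes, found the initiation list lower in HT29 (adjusted p = 0.00055) and past no threshold in PC9 (adjusted p = 0.921). Of 17 genes of autophagosome conjugation 1 was lower in colon, the protease gene ATG4C at −1.01, and 0 were called in lung (adjusted p = 0.962 and 0.957). The ATG4C call was lost under quantile normalization (−0.98), under median centring (−0.99) and without replicate 2 (−0.98) or replicate 3 (−0.98) of HT29 or replicate 1 (−0.99) or replicate 3 (−0.99) of HCT15. Of 13 selective autophagy receptors, RETREG1 was lower in HT29 (−1.20) and BNIP3 lower in PC9 (−1.02), with adjusted p-values of 0.932 and 0.905. Among genes given whatever their values, the kinase gene ULK1 differed by −0.04 in colon and 0.12 in lung, the receptor gene SQSTM1 by 0.43 and 0.14, MAP1LC3B by −0.01 and −0.41, and the thioesterase gene PPT1 by 0.05 and 0.06. For TFEB, a regulator of lysosomal genes, the values were 0.36 and 0.28, for CTSD 0.68 and 0.42, and for LAMP1 0.10 and 0.27, and 0 of these 7 genes were called in either tissue.

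Several lysosomal genes were lower in the sensitive lines. The lysosomal hydrolases had 4 of 37 members lower and 2 higher in HT29 (adjusted p = 0.458), with GALC at −4.41, CTSL at −1.82, SMPD1 at −1.78 and the glycogen-degrading GAA at −1.73. In PC9 7 members were lower and 0 higher, with GALC at −4.48, CTSS at −2.86, GAA at −1.69 and CTSB at −1.53 (adjusted p = 0.0171; adjusted p = 0.763 with an estimated correlation). The colon list had a median of 0.18 and a mean of −0.10. In the MiT/TFE and mTORC1 list, MITF, a transcription factor related to TFEB, was lower by −1.46 in HT29 and −2.06 in PC9, and RRAGD was lower in both, while 2 of 28 members were higher in each tissue (adjusted p = 0.767 and 0.0619). The 2 higher members in HT29 were SESN3 and SESN1. Of 21 V-ATPase subunits, which acidify lysosomes, 2 were lower in HT29, ATP6V1C2 (−2.88) and ATP6V0A1 (−1.14), with an adjusted p of 0.0229 (adjusted p = 0.508 with an estimated correlation). In PC9 ATP6V0D2 was higher (1.40) and ATP6V1C1 lower (−1.22), with an adjusted p of 0.387. Lysosomal membrane genes were lower in 3 of 29 members in HT29, the channel genes MCOLN2 (−3.68) and MCOLN3 (−3.43) and LAMP3 (−2.42), with an adjusted p of 0.0798. In PC9 3 members were lower and 2 higher, with LAPTM5 at 3.19 and the cholesterol exporter gene NPC1 at −1.14 (adjusted p = 0.666). In the average the membrane list reached an adjusted p of 0.0496 (adjusted p = 0.63 with an estimated correlation) and the V-ATPase list 0.0163 (adjusted p = 0.464 with an estimated correlation).

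**Figure D3:**
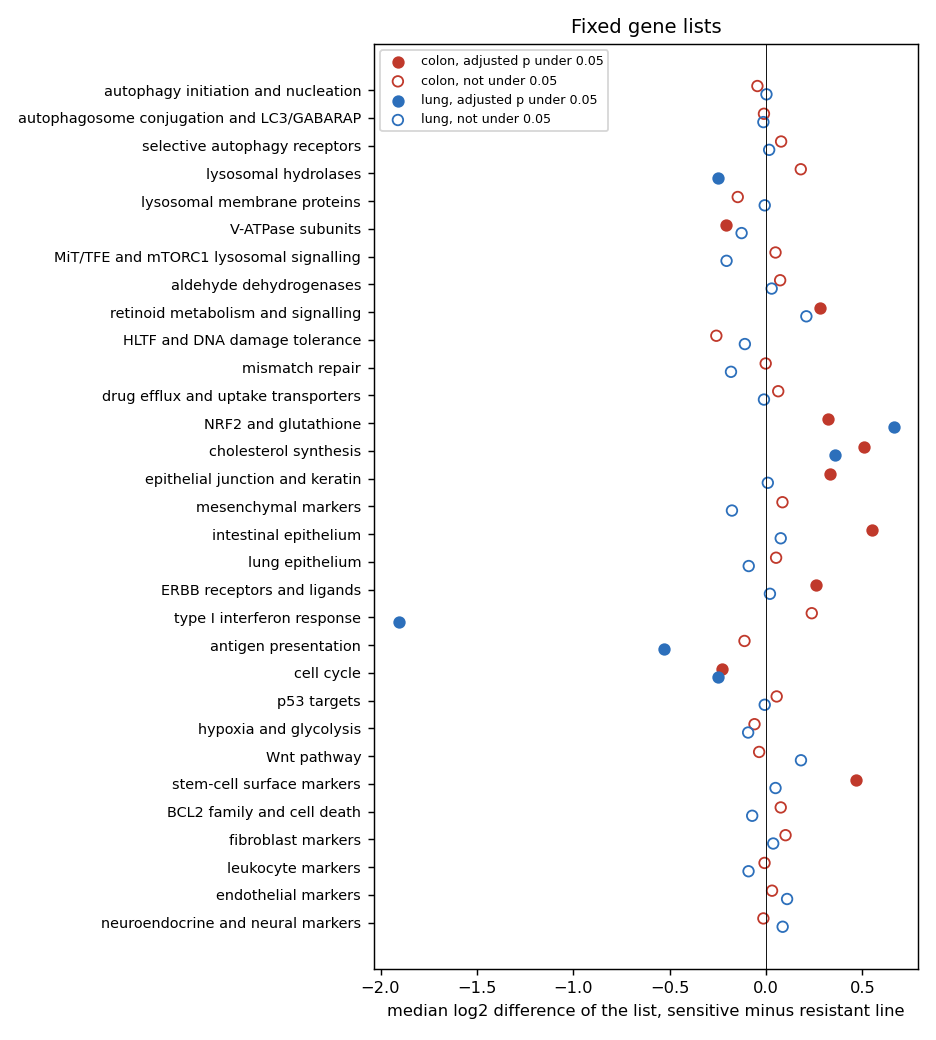
Median log2 difference between the sensitive and the resistant line for 31 gene lists in colon (red) and lung (blue), with filled points where the camera adjusted p with its preset correlation was under 0.05. The type I interferon response sits at −1.91 in lung and 0.24 in colon, and the autophagy lists lie near 0.

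ALDH1A1 and HLTF, given whatever their values, were called in colon and not in lung. ALDH1A1 stood at 4.81 ± 0.11 in PC9 and 4.78 ± 0.01 in HCC827 (mean ± SD, n = 3 each), a difference of 0.03 with an adjusted p of 0.739. These levels and that of HCT15 are dim against a median level of 7.41, so a difference between the lung lines below background would not be seen. HLTF differed by −0.26 in lung, with an adjusted p of 0.0272 and below the 2-fold minimum, and the difference between tissues was called for both genes, at 7.26 for ALDH1A1 and −5.29 for HLTF. Of 19 aldehyde dehydrogenases 4 were higher and 1 lower in each tissue, and ALDH3A1 (1.40 and 3.01) and ALDH3A2 (1.30 and 1.37) were higher in both (adjusted p = 0.274 in colon and 0.903 in lung). Of 20 genes of the HLTF and DNA damage tolerance list 1 was called in colon, HLTF itself, and 0 in lung, with adjusted p-values of 0.101 and 0.695. EGFR, the growth factor receptor gene, differed by 0.04 in colon and −0.83 in lung, and the epithelial cadherin gene CDH1 by 0.51 and −0.65, and both stayed below the 2-fold minimum.

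The interaction asked which differences between phenotypes were unequal in colon and lung. With 1 line of each phenotype per tissue, it cannot tell such an inequality from differences between single lines. DPP4 was higher in HT29 (4.05) and lower in PC9 (−6.74), HHLA2 followed at 5.13 and −5.44, and the coagulation inhibitor gene TFPI at 4.26 and −5.04. SERPINA1 (3.25 and −4.75), TOX3 (3.97 and −3.52) and the bicarbonate transporter gene SLC4A4 (4.01 and −3.17) shared this orientation. LEF1 (−5.89 and 3.25), SLC2A3 (−5.16 and 2.84), GDPD3 (−3.06 and 3.62), GPR63 (−2.89 and 3.98), CPA4 (−2.85 and 2.81) and NLRP2 (−2.60 and 4.42) were lower in HT29 and higher in PC9. In total 2589 genes were called, 1355 with a higher and 1234 with a lower difference in colon. Of the genes called in opposite directions, 119 were higher in HT29 and 73 higher in PC9. The interferon response had 23 of 36 members called with a higher difference in colon than in lung and 2 with a lower one (adjusted p = 1.46e-10; adjusted p = 0.229 with an estimated correlation). The corresponding called members were 11 and 3 of 28 for intestinal epithelium (adjusted p = 0.00897; adjusted p = 0.229 with an estimated correlation) and 6 and 1 of 37 for lysosomal hydrolases (adjusted p = 0.0441; adjusted p = 0.775 with an estimated correlation). In colon the interferon list had 8 members higher and 5 lower, with SAMD9 at 2.53 and HERC5 at −2.91, and an adjusted p of 0.411.

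The study's own gene lists were chosen on these samples, so their direction is not independent evidence. The authors' deposited table lists 122 probe sets as increased in sensitive lines, of which 122 were called higher in colon and 44 in lung as well. The authors' deposited table lists 103 as decreased, of which 103 were called lower in colon and 39 in lung as well. Of 7 autophagy probe sets in the authors' deposited table, 0 were called in either tissue. From the authors' short table of genes higher in sensitive lines, LYZ (8.46 and 2.66), GPX2, AKR1B10, CALB2, NTSR1, the aspartic protease gene CTSE (5.40 and 1.51), SERPINB5 (4.79 and 2.48), the cholesterol transporter gene GRAMD1B (4.88 and 1.64) and the iron exporter gene SLC40A1 (4.97 and 1.01) were called higher in both tissues. The lung call of SLC40A1 was lost without replicate 2 (0.99) or replicate 3 (0.97) of PC9 or replicate 2 of HCC827 (0.98).

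The colon lines were also compared with the lung lines. NPNT, an extracellular matrix gene, was higher in the colon lines by 4.48 ± 0.085 (SE, n = 6 and 6 arrays of 2 lines per tissue) and RNF43, an inhibitor of Wnt signalling, by 3.69, and IQGAP2 (3.62), TENM3 (3.60), ALDH1A1 (3.57), QPCT (3.54), VSNL1 (3.51) and ID2 (3.48) followed. The ALDH1A1 value came from HT29 alone, since HCT15 lay at the dim level of the lung lines. The ID2 value came largely from a low level in PC9. The oncostatin M receptor gene OSMR was lower in the colon lines by −6.88 and the actin-bundling LCP1 by −6.43. RAB31 (−6.18), the fatty acid elongase gene ELOVL5 (−6.13), CALB1 (−6.10), the mitophagy receptor gene BNIP3 (−6.08), SNAI2, a transcription factor of mesenchymal transition (−6.03), and CD109 (−5.77) were lower too. In total 1529 genes were called, 545 higher and 984 lower in the colon lines. With the 4 line means as the unit, a fit with little power, limma called 0 genes here (smallest adjusted p 0.405). With cell line as a random block, where arrays still count as samples, it called 1408. Intestinal epithelium had 11 of 28 members higher and 1 lower (adjusted p = 0.000562; adjusted p = 0.154 with an estimated correlation), and cell cycle 5 of 40 higher (adjusted p = 1.22e-07; adjusted p = 0.191 with an estimated correlation). Mesenchymal markers had 11 of 28 lower (adjusted p = 2.18e-06; adjusted p = 0.162 with an estimated correlation) and hypoxia and glycolysis 8 of 28 lower (adjusted p = 1.22e-07; adjusted p = 0.162 with an estimated correlation). Wnt pathway genes (adjusted p = 0.0489) were higher, with 7 of 30 called higher and 2 lower, and NRF2 and glutathione (0 of 25 higher, 6 lower, adjusted p = 0.00572) and retinoid genes (1 of 20 higher, 4 lower, adjusted p = 0.0415) were lower, each with an adjusted p = 0.162 with an estimated correlation. Lysosomal membrane genes were lower, with 2 of 29 called lower and 0 higher (adjusted p = 0.0326). The HLTF and DNA damage tolerance list had a median of 0.37 (adjusted p = 0.0356), while 0 of its 20 members were called higher and 1 lower, HLTF at −1.87, each list with an adjusted p = 0.524 with an estimated correlation. The HLTF value came from HT29, where HLTF was low, and not from HCT15. RNA quality sheets record separate submissions to the array facility, and the samples of 1 of them are given by number only, so tissue and submission may coincide.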

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

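The tests on splits of the arrays, on the balance of shared and opposed genes and on the scaling and level of HLTF were chosen only after the results were seen, and the test on the neighbours of HLTF before.

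Differences between the sensitive and the resistant line were unequal in colon and lung by the interaction test for 2589 genes. With 1 line of each phenotype per tissue, an effect of tissue on the phenotype difference cannot be told apart from differences between single lines. Each value here is the colon log2 difference minus the lung one. It was 10.79 for DPP4, 10.57 for HHLA2, 9.30 for TFPI, 7.998 for SERPINA1, 7.49 for TOX3 and 7.18 for SLC4A4, and −9.14 for LEF1, −8.01 for SLC2A3, −7.03 for NLRP2, −6.87 for GPR63, −6.68 for GDPD3 and −5.66 for CPA4. Background limits the size of these values where a line is dim, as for HHLA2 (4.92 in HCT15 and 4.98 in PC9) and DPP4 (5.42 in PC9), so their exact size and order stay open. Among the genes given whatever their values it was 7.26 for ALDH1A1, −5.29 for HLTF, 3.13 for VIM and 1.17 for CDH1. By list the interaction reached an adjusted p of 1.46e-10 for the type I interferon response, 0.00897 for intestinal epithelium and 0.0441 for lysosomal hydrolases, and with an estimated correlation these were 0.229, 0.229 and 0.775. Probe sets without a single gene symbol, which were tested but do not enter the gene counts, were called in 172 cases in colon and 256 in lung.

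Within colon the real split gave 1449 genes and the highest of the others 0, and within lung 1504 and 0. Each is 1 of 10 splits, too few for a share under 0.05. Over both tissues, the splits with a count as large as the real one were 1 of 100 for the average (989 genes, highest other split 872), 1 of 100 for the genes shared in direction (250, highest other 192), 2 of 100 for those opposed (192, highest other 250), 2 of 100 for the interaction (2589, highest other 2942) and 1 of 100 for the colon against the lung lines (1529, highest other 872). Nearly all of these splits mix arrays of different lines in a group, which widens the spread, so the low counts bear on single arrays and not on the lines. The exchange of the phenotype labels of the lung lines keeps each line whole, and it gave the highest other count in the 4 sets within tissues. Chance in which line carries which phenotype is therefore not excluded.

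More genes were shared in direction (250) than opposed (192), a ratio of 1.3. Exchanging the phenotypes in 1 tissue would turn the opposed genes into shared ones, and whole lines allow no other assignment, which is too few to test the ratio. Differences between unrelated lines whatever their phenotype and a part that belongs to drug sensitivity cannot be told apart, with 1 line of each phenotype per tissue. The 4 line means, a fit with little power, called 0 genes, which leaves the shared genes as candidates.

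HLTF was lower in HT29 than in HCT15 by −5.55. Loss of the surrounding chromosomal region might lower neighbouring genes as well, and predicted a median below −0.5 for the 10 nearest expressed genes on each side. The median of these 20 neighbours was 0.267, with 2 below 0, which argues against such a loss. Quantile normalization or median centring, which changed other calls, shrank the difference by at most 0.017. Of the 2349 genes within 0.5 of the HCT15 level of HLTF, 0 had a difference as low (lowest −4.49). The deposited arrays were already normalized with close medians, and HLTF was known to be among the lowest genes in colon. Both outcomes were therefore largely fixed in advance. They do not decide on a difference in scale or a normalization that shifts genes of the same level alike. A deletion of HLTF alone, silencing of its promoter or a probe that misses a variant in HT29 stays open, and no other biological explanation was tested.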

How the results depend on the processing

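The alternatives here were chosen before the results were seen, except the cell-line fits between tissues, which were chosen after seeing the data. Under quantile normalization, median centring, the filter on dim probe sets, eBayes with trend, the unmoderated model, averaged probe sets and the workbook's values, each count of called genes stayed within 1.5 times its value and kept its direction. The arrays of 1 tissue alone give only the colon and the lung count, and both kept to this. The workbook's values equal those used here, so they could change nothing. The eBayes settings, the unmoderated model and the arrays of 1 tissue keep the same log2 differences. They could move a count only through the adjusted p. In the main limma fit the largest adjusted p of a called gene was 0.000898 in colon, 0.00196 in lung and 6.82e-05 in the average. It was 0.0039 in the interaction and 1.81e-05 between tissues. All lie far under the threshold, so these refits had little room to remove a call. Their steady counts therefore say little about robustness. The filter left 14859 probe sets whose mean in at least 1 line reached 7.41, the median of all probe-set means, and signal near background limits dimmer ones.

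With the adjusted p alone the counts were 8659 in colon, 9430 in lung, 9863 in the average, 9196 in the interaction and 10909 between tissues, with 3286 shared in direction and 2671 opposed, since the fold minimum was dropped. With limma treat, which tests against the 2-fold minimum and is stricter by construction, the interaction called 1664, and 154 genes were shared and 121 opposed. The 4 cell line means called 0 genes (limma, smallest adjusted p 0.824, 1319 at an unadjusted p under 0.05), with fewer samples and little power. Cell line as a random block called 758, with a consensus correlation of 0.582, a smallest adjusted p of 2.91e-12 and 5381 genes at an unadjusted p under 0.05. That fit shares the correlation among all genes and still counts arrays as samples, so its calls do not stand for replication across lines. Between tissues, the 4 cell line means called 0 genes (smallest adjusted p 0.405, 2320 at an unadjusted p under 0.05) and cell line as a random block 1408.

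Leaving out each array in turn gave 1436 to 1461 genes in colon, 1473 to 1543 in lung, 978 to 1006 in the average, 2576 to 2607 in the interaction, 1522 to 1546 between tissues, 244 to 258 shared and 189 to 195 opposed, and a correlation of 0.036 to 0.045 (jackknife SE 0.00742).

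Lists past the threshold numbered 9 in colon, 3 with an estimated correlation and 24 with fry. In lung they were 6, 2 and 20, in the average 10, 4 and 27, in the interaction 3, 0 and 26, and between tissues 9, 0 and 30. Fry does not set a list against other genes, and the cause of the losses with an estimated correlation was not tested.

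Of 383 called values of named genes, 0 changed sign in any setting and 8 lost the call when an array was left out. In other settings 33 lost it, cell-line settings left aside, of which 32 under treat. With cell line as a random block 11 of 99 lost the call of the average. Values that reversed were uncalled and near 0. MAP1LC3B in colon went to 0.002 under quantile normalization, 0.002 under median centring, 0.025 without HT29 replicate 3 and 0.048 without HCT15 replicate 2 (range over arrays left out −0.043 to 0.048). PPT1 in colon went to −0.008 under quantile normalization, EGFR in colon to −0.082 without HT29 replicate 2 (range −0.082 to 0.134) and ALDH1A1 in lung to −0.018 without PC9 replicate 3 (range −0.018 to 0.087). The cause was not tested.

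With the replicate number as a block the counts were 1449 in colon, 1504 in lung, 989 in the average, 2589 in the interaction and 1529 between tissues. Every line has the same replicate numbers, so the block cannot change the log2 differences, and equal counts say little about pairing. Over 6 pairs of equal number within a tissue, deviations from line means correlated at a median of 0.013 (−0.055 to 0.164). Over 12 pairs of unequal number within a tissue the median was 0.008 (−0.18 to 0.22). No clear pairing was seen, but these correlations are few and not independent, so pairing stays open.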

Other observations

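The tests of gene order along chromosomes were chosen before their results were seen.

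Drug transporter genes differed in both directions. ABCG2, an efflux pump, was higher in the sensitive line by 2.60 in colon and 1.84 in lung, while ABCB1 was lower by −4.88 and −1.09. Of 20 measured transporters 5 were higher and 4 lower in colon and 3 higher and 3 lower in lung (camera adjusted p = 0.937 and 0.957), and in colon their median was 0.06 and their mean −0.24. Of 6 mismatch repair genes, MSH6, a mismatch recognition subunit, was higher in HT29 by 2.35 and MLH3 lower by −1.76, and 0 were called in lung (adjusted p = 0.962 and 0.616). Retinoid genes in lung had 3 of 20 members higher and 2 lower, with RARRES1 at 3.75 and PLAAT4 at −4.78 (adjusted p = 0.523), and PLAAT4 was higher in colon at 1.99. Epithelial junction and keratin genes in lung had 4 of 28 members higher and 2 lower, with the basal keratin gene KRT5 at 4.999 and CLDN3 at −1.57 (adjusted p = 0.957). The ERBB list in lung had 6 of 25 higher and 2 lower, with HBEGF at 1.52 and EREG at −3.43 (adjusted p = 0.957).

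Wnt pathway genes were higher in 4 and lower in 5 of 30 members in colon and higher in 4 in lung, where the secreted inhibitor gene SFRP1 stood at 3.64 (adjusted p = 0.932 and 0.127). Of 25 p53 targets 3 were higher and 1 lower in colon, with GDF15 at 2.33, and 1 was lower in lung, TP53INP1 at −2.47 (adjusted p = 0.596 and 0.905). Hypoxia and glycolysis had 2 higher and 1 lower of 28 in colon and 1 higher and 4 lower in lung (adjusted p = 0.728 and 0.568). The cell death gene PMAIP1 was lower in both sensitive lines, at −1.29 and −1.21, in a BCL2 family list of 28 (adjusted p = 0.458 and 0.862). Antigen presentation in colon had 2 higher and 4 lower of 18 (adjusted p = 0.163), mesenchymal markers 3 higher and 3 lower of 28 (adjusted p = 0.522) and lung epithelium 1 higher and 3 lower of 23 (adjusted p = 0.82). In lung, intestinal epithelium had 4 higher and 3 lower of 28 (adjusted p = 0.568) and stem-cell markers 1 and 1 of 19 (adjusted p = 0.617). Markers of other cell types did not pass as lists in colon or lung: fibroblast (adjusted p = 0.408 and 0.949), leukocyte (0.86 and 0.658), endothelial (0.596 and 0.523) and neuroendocrine and neural (0.681 and 0.568). Single members did differ, with LUM at 3.53 in colon, CD79A at −1.99, PECAM1 at 2.24 and UCHL1 at 5.01 in lung.

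Neighbouring genes differed together. Of 546 windows of 20 consecutive expressed genes, 12 had a median difference beyond 0.5 in colon, 4 higher and 8 lower in HT29, and the highest of 100 shuffles of gene order gave 1. In lung 41 of 561 windows lay beyond 0.5, 17 higher and 24 lower in PC9, against 1 in the highest shuffle, so chance order of genes was excluded in both. Gains and losses of chromosome segments, which cancer lines are known to carry, may account for part of this, and shared regulation of neighbouring genes stays open, since DNA copy number was not analysed here.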
